A study of Brassica napus with 6 samples.

How the data were processed

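Poly-A RNA from individual very young leaves, the third of each plant, of the hairy and the glabrous Brassica napus line was sequenced as paired ends with inserts of 300 ± 50 bp, from RNA with an integrity number over 7, and plants were kept at 16 h light and 8 h dark. The labels list 6 leaves, 3 per line, while the design text gives 2 per line. The table has columns for replicates 1 and 3 of each line, and the replicate 2 leaves were not used here. The submitters' processing notes name cutadapt 1.9. The file and column names are those of CLC software; aligner, genome build and annotation are not given in the sources used here.

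The deposited table gives values in TPM per transcript model and leaf, computed by the authors. It holds 185771 transcript models of 145279 genes, of which 99507 genes carry an Arabidopsis match. The authors' mean TPM per line differs from the mean of the leaf columns in 0 transcripts, at a tolerance of 1e-06 TPM. The deposited larger of the authors' group means is a signal on the TPM scale. The authors also deposited a signed fold change and a log2 fold change of hairy over glabrous, a p-value and a false discovery rate adjusted p-value per transcript, whose test is not stated. TPM carry no read counts, so the depth per leaf is unknown and no counting interval can be given; precision rests on the spread between 2 leaves per line. The test planned for counts could not be used, and the one planned for TPM was.

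TPM were summed over the transcripts of each gene. Genes with at least 1 TPM in at least as many leaves as the smaller group (2) were tested, 44247 in all, by limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a variance trend and robust shrinkage, and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Log2 changes are hairy minus glabrous on this scale, which shrinks differences near 0 TPM. The median SE was 0.46. The method was tested on simulated data with 200 changed genes: of 67 genes changed by 1, 67 by 2 and 66 by 4 on the log2 scale, 1, 44 and 66 were recovered, and 8 unchanged genes were called.

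Before the data were examined, 17 gene lists were fixed in Arabidopsis identifiers and joined through the table's matches. Each was tested with camera (preset correlation 0.01), with camera at an estimated correlation, and with fry. At the estimated correlation every tested list had the same adjusted p of 0.984, so that value does not tell one list from another. Calls per chromosome used Fisher's exact test (two-sided), and windows of 50 genes were set against 10000 shuffles. Order along a chromosome was taken from gene identifiers: in 82.3% of pairs of neighbours by identifier, the Arabidopsis matches lie within 50 steps of each other by identifier number, against 1.50% after shuffling. Dense runs, defined after the calls had been seen, are joined windows with more calls than any shuffle gave, trimmed to their first and last called gene. Terms are the EggNOG descriptions with 10 to 500 tested genes, tested one-sided. Copies are genes that share an Arabidopsis match, and reads of near-identical copies may be placed on either. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used.

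The genes named were fixed by rule: all tested copies of 8 core trichome genes, at most 12 called copies from the 3 trichome lists, the 6 higher and 6 lower called genes with the largest change, an Arabidopsis match, a mean of at least 5 TPM in the higher line and no overlap between the lines, at most 2 called copies of each other list, and at most 3 members of the 2 leading terms each way. The sums of PR1, PR2, NPR1, PAD4, MYB51, LHCB1.1, LHCA1 and RCA were named after their values were seen. Alternatives were each leaf left out, the replicate number as a block, other scalings, filters, pseudocounts, variance priors, window sizes and correlations. Added after seeing the data were a crossed pairing, a fit per transcript, sums over copies for the gene counts and terms, and fits outside the dense runs. The leave-one-out fits first required 1 TPM in 2 leaves. After their results had been seen, this was changed to the size of the smaller group, 1 leaf, as the plan words it. Both versions are given. A check of gene length was void, because only 64.5% of tested genes match the reference gene table of the Da-Ae assembly.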

Results

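Transcript levels were measured by poly-A RNA sequencing in single, very young leaves, the third of each plant, of a pair of near-isogenic doubled haploid lines of Brassica napus, an allotetraploid with an A and a C subgenome. The hairy line, DH6-47, carries about 600 trichomes per leaf per the labels, and DH6-110 is labelled glabrous. Values were available for replicates 1 and 3 of each line, so every comparison below sets 2 leaves against 2, and means are given with the SD over 2 leaves. The replicate 2 leaves were not analysed here. The values were TPM, transcript abundances scaled to a common total, which sum to 962645 in hairy 1, 954905 in hairy 3, 954250 in glabrous 1 and 955729 in glabrous 3. The sequencing depth behind them is unknown. At 1 TPM or more, 42474 genes were seen in hairy 1, 40929 in hairy 3, 39919 in glabrous 1 and 43209 in glabrous 3. Across genes, the log2 values correlated at r = 0.948 between the hairy leaves, 0.909 between the glabrous leaves and 0.747 to 0.80 between leaves of different lines; genes are not independent replicates.

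The comparison of the lines asks which genes differ in a leaf that does or does not form trichomes. Of 25 copies of defence genes, 14 were higher in the hairy line and none lower. With an estimated correlation the list's camera p was 0.0833, and its adjusted p of 0.984 was that of every tested list. Of 35 copies of trichome activator genes 2 were higher and 2 lower, and of 22 copies of inhibitor genes 1 was higher and 2 lower. Whether these trichome lists hold fewer calls than other genes was not tested. In the limma fit on log2(TPM + 1), 2319 of 44247 tested genes were higher and 1982 lower in the hairy line at an adjusted p under 0.05, and all of them by more than 2-fold. At an unadjusted p under 0.05 there were 7688. In 63.7% of the called genes, the mean of one line lay under 1 TPM, against 12% of the tested genes. The p-values rest on the spread between single leaves. Leaving out hairy 1 gave 723 higher and 690 lower genes, and leaving out hairy 3 gave 785 and 641; without glabrous 1, 1068 genes were higher. In simulated data with as many genes, of which 200 were changed, 1.49% of genes changed by 1 on the log2 scale were recovered and 65.7% of those changed by 2. More genes were called in the data, which loosens the adjusted threshold, so these shares may be too low for the data. Changes near 1 were still mostly not detectable with 2 leaves per line, as every call was over 2-fold. With the replicate number as a block, 1834 genes were higher and 1704 lower.

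Among the core genes that start or repress trichome fate, none of the 18 tested copies of GL1, GL3, EGL3, TTG1, GL2, TRY, CPC and TCL1 passed the threshold. The 2 copies of GL2, a homeodomain gene that acts in trichome outgrowth, had the largest differences. The A07 copy (BnaA07g032930.4DH) read 1.92 ± 0.29 TPM in the hairy and 0.43 ± 0.52 TPM in the glabrous line (log2 change 1.07, adjusted p = 0.183), and the C06 copy (BnaC06g041430.4DH) 1.84 ± 0.62 and 0.22 ± 0.19 TPM (2.30-fold on the TPM + 1 scale, adjusted p = 0.0935). Summed over its copies, GL2 changed by 1.59 (limma adjusted p = 0.164). The other 16 copies lay between -0.49 and 0.68 on the log2 scale. GL1, the MYB gene that starts trichomes in Arabidopsis, had 1 tested copy, with 2.54 ± 1.39 TPM in the hairy and 2.32 ± 0.00 TPM in the glabrous line.

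Of the 35 tested copies of trichome activator genes, 2 were higher and 2 lower in the hairy line, and the same numbers passed when adjusted over the list alone. These counts changed with the scaling: quantile normalization gave 1 higher and 4 lower (6 and 6 adjusted over the list alone), and TMM-like scaling 1 and 3 (7 and 6). The median log2 change of the list was 0.08 (camera adjusted p = 0.912). TTG2 (BnaA03g020900.4DH), a WRKY gene that acts downstream of the trichome initiation complex, read 4.04 ± 0.33 TPM against 0.66 ± 0.45 TPM (log2 change 1.62, SE 0.45, adjusted p = 0.0411). MYB23 (BnaA04g018510.4DH), a relative of GL1, read 2.71 ± 2.27 TPM against 0.08 ± 0.11 TPM (1.64, SE 0.47, adjusted p = 0.0499). Lower in the hairy line were GIS (BnaA07g030260.4DH; sum over copies -0.82, not past the threshold), a zinc finger gene that links gibberellin to trichome initiation, at 0.61 ± 0.68 against 4.70 ± 0.46 TPM (-1.89, adjusted p = 0.0247), and HDG11 (BnaC06g062850.4DH; sum -0.50, not past it) at 0.07 ± 0.03 against 6.43 ± 6.76 TPM (-2.42, adjusted p = 0.026). Summed over copies, none of the 13 activator genes passed over all genes. When adjusted over the list alone 3 were higher and 0 lower: GL2 (1.59), MYB23 (1.64) and TTG2 (1.65). With 1 leaf left out in turn and the planned filter, limma called 0 activator copies higher and 0 to 1 lower, against 2 to 7 higher and 2 to 5 lower at an unadjusted p under 0.05. The 2-library filter asks for 1 TPM in at least 2 of the 3 leaves; it was the first version of these fits, replaced after its results had been seen and kept as an alternative. With it limma called 0 to 2 higher and 0 to 1 lower (0 to 8 and 1 to 3 unadjusted). The call was lost in 10 of 14 alternative settings for MYB23, 9 of 14 for TTG2, 8 of 16 for GIS and 8 of 14 for HDG11.

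**Figure D1:**
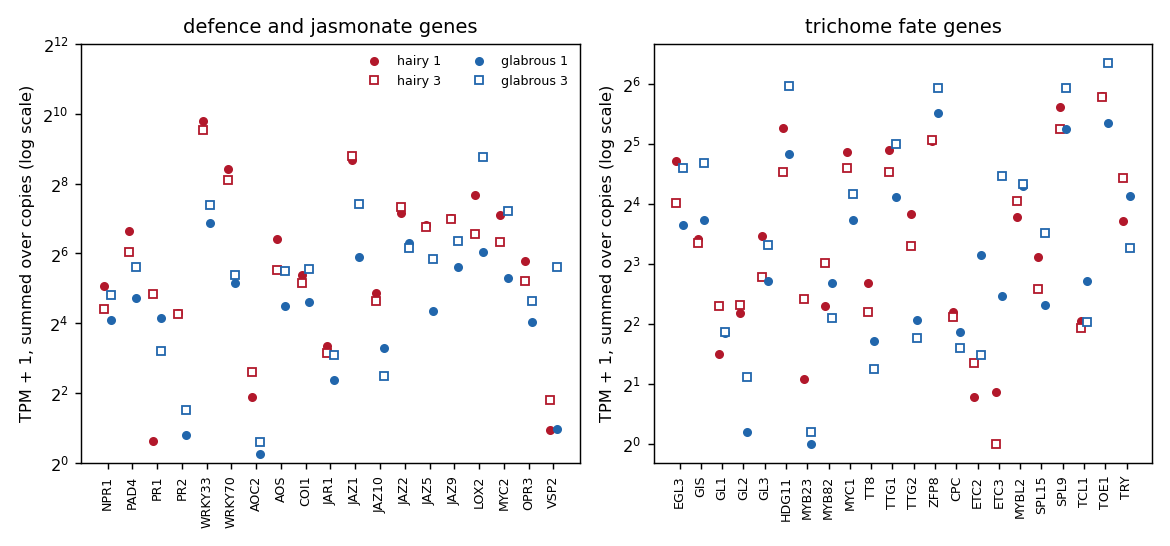
TPM + 1 summed over all copies of each Arabidopsis gene, on a log axis, for defence and jasmonate genes (left) and for trichome fate genes (right). Each symbol is 1 leaf: red for hairy, blue for glabrous, filled for replicate 1 and open for replicate 3. The sums past the threshold over all genes are WRKY33, WRKY70, PR2 and JAZ1, higher in both hairy leaves than in both glabrous leaves, and ETC3, lower. Other sums separate the lines without passing, such as PAD4, JAZ2, GL2, TTG2 and MYB23 (higher) and GIS and ZFP8 (lower).

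Of 22 copies of trichome inhibitor genes, 1 was higher and 2 lower, with the same counts adjusted over the list alone (median 0.01, mean -0.29, camera adjusted p = 0.425); the median was -0.06 after quantile normalization and -0.02 after TMM-like scaling. ETC3 (BnaA03g032400.4DH), a single-repeat MYB gene that represses trichome fate, read 0.30 ± 0.43 TPM in the hairy and 10.7 ± 9.15 TPM in the glabrous line (log2 change -2.94, SE 0.60, adjusted p = 0.00724). It was the only tested copy of its gene, and the sum over copies also passed (-3.03, adjusted p = 0.0171). Without hairy 1 or without hairy 3 the call of the copy was lost (adjusted p = 0.0898 and 0.21). The copies of MYBL2, another MYB repressor, went opposite ways. The C06 copy (BnaC06g060100.4DH) read 0.07 ± 0.09 TPM in the hairy against 16.1 ± 1.18 TPM in the glabrous line (-4.01, adjusted p = 1.72e-04), the A07 copy (BnaA07g044150.4DH) 14.1 ± 2.12 against 2.81 ± 0.75 TPM (1.99, adjusted p = 0.0162). The log2 change of the sum was -0.41 and did not pass. The call of the A07 copy was lost in 7 of 17 settings.

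Of 59 copies of genes for trichome branching and wall maturation, 2 were higher, none lower, and the same 2 passed adjusted over the list alone (median 0.04, camera adjusted p = 0.941). At an unadjusted p under 0.05, 3 were higher and 2 lower. With 1 leaf left out and either filter, limma called 0 to 3 higher and 0 to 2 lower, against 2 to 9 higher and 0 to 5 lower at an unadjusted p under 0.05. PIR (BnaC03g011230.4DH), part of an actin-regulating complex, read 13.5 ± 5.87 TPM against 1.80 ± 1.18 TPM (2.38, SE 0.53, adjusted p = 0.012), while the log2 change of its sum over copies was 0.72 and did not pass. A copy of SIM (BnaS00029g0540.4DH), an inhibitor of division in trichome cells, read 3.05 ± 0.83 TPM in the hairy line and is listed at 0 in both glabrous leaves (adjusted p = 0.0062), and its sum over copies did not pass (-0.52).

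Of the 25 tested copies of defence genes, 14 were higher in the hairy line and none lower, and 17 were higher when adjusted over the list alone. The median log2 change was 1.58 (camera adjusted p = 2.71e-13). With an estimated correlation camera gave p = 0.0833, and 0.984 after adjustment, the value of every tested list. Fry's adjusted p was 0.18. The A05 copy of WRKY33 (BnaA05g007320.4DH), a transcription factor of pathogen responses, read 158 ± 14.2 TPM in the hairy against 9.18 ± 3.59 TPM in the glabrous line (4.01, SE 0.38, adjusted p = 4.81e-05). The C06 copy of WRKY70 (BnaC06g036120.4DH), which acts in salicylate signalling, read 72.1 ± 18.5 TPM against 3.21 ± 0.61 TPM (4.10, SE 0.40, adjusted p = 5.74e-05). Summed over copies, WRKY33 changed by 2.53 (adjusted p = 0.00115), WRKY70 by 2.97 (adjusted p = 3.01e-04) and PR2, a salicylate-induced glucanase, by 3.13 (adjusted p = 0.00421). The log2 changes of the NPR1 and PAD4 sums were 0.29 and 1.17 (adjusted p = 1.00 and 0.276). The sum of PR1, the usual marker of salicylate responses, read 0.55 TPM in hairy 1, 27.7 in hairy 3, 16.7 in glabrous 1 and 8.27 in glabrous 3. None of the 14 called defence copies lies in the dense runs described below, and the number of higher copies fell to 9 without hairy 1 (8 with the 2-library filter, also without hairy 3). With no low-value filter the list's median was 0.65 (camera adjusted p = 3.44e-08).

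Of 51 copies of jasmonate genes, 12 were higher and 4 lower, and 18 were higher and 4 lower adjusted over the list alone. The median was 0.76 (camera adjusted p = 0.00259). Camera with an estimated correlation gave p = 0.431, and 0.984 after adjustment, and fry's adjusted p was 0.814. JAZ1, a repressor that jasmonate itself induces, was higher in its A06 copy (BnaA06g016350.4DH) at 53.4 ± 4.78 against 3.13 ± 0.34 TPM (3.72, SE 0.40, adjusted p = 9.65e-05) and in its sum (2.07, adjusted p = 0.019). The C06 copy of JAZ2 (BnaC06g064340.4DH) read 23.2 ± 0.64 TPM in the glabrous line and is listed at 0 in both hairy leaves (adjusted p = 7.32e-05), while the log2 change of the JAZ2 sum was 1.03 (adjusted p = 0.204). Without hairy 1 there were 1 higher and 2 lower copies, without hairy 3 there were 2 and 1, without glabrous 1 there were 5 and 9, and without glabrous 3 there were 15 and 4. With the 2-library filter these were 7 and 6, 5 and 3, 10 and 6, and 20 and 1. Leaving out glabrous 1 lowered the list's median to 0.22 (adjusted p = 0.421), and leaving out hairy 3 ended its call with the planned filter (median 0.81, adjusted p = 0.0732) but not with the 2-library filter (median 0.93, adjusted p = 0.0013). Dropping the low-value filter also ended it (median 0.40, adjusted p = 0.12).

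Of 25 copies of photosynthesis genes, 1 was lower in the hairy line and none higher, also adjusted over the list alone, and at an unadjusted p under 0.05 there were 6 lower and 0 higher. The median was -0.71 (camera adjusted p = 9.01e-05). Camera with an estimated correlation gave p = 0.297, and 0.984 after adjustment, and fry's adjusted p was 0.448. The A09 copy of PSBO1 (BnaA09g010280.4DH), a subunit of photosystem II, read 95.5 ± 18 TPM in the hairy and 374 ± 39.6 TPM in the glabrous line (-1.97, adjusted p = 0.00716). The log2 changes of the LHCB1.1, LHCA1 and RCA sums were -0.86, -0.89 and -0.79. In the limma fit none of the 7 sums passed; PSBO1 had -0.60. Without glabrous 1, 14 copies were lower when adjusted over the list alone. With the 2-library filter, 12 were lower over all genes without glabrous 1, and the list's call was lost without hairy 1 (median -0.68, adjusted p = 0.241).

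Stomatal lineage genes had a median of -0.51 (camera adjusted p = 0.0406, and 0.203 with the replicate number as a block). Camera with an estimated correlation gave p = 0.306, and 0.984 after adjustment, and fry's adjusted p was 0.703. Of 19 copies 1 was lower and none higher, also adjusted over the list alone. That copy was TMM (BnaA07g033100.4DH), a receptor-like protein of stomatal spacing, at 7.32 ± 1.79 against 25.8 ± 4.66 TPM (-1.69, adjusted p = 0.0202; sum -1.65, adjusted p = 0.0961), a call lost in 8 of 17 settings. Vascular genes had a median of -0.64 (camera adjusted p = 0.0279, and 0.0897 with the block). Camera with an estimated correlation gave p = 0.553, and 0.984 after adjustment, and fry's adjusted p was 0.929. Only 1 copy of 19 was lower, also adjusted over the list alone. It was XCP2 (BnaC04g014040.4DH), a xylem protease, at 0.18 ± 0.25 against 4.95 ± 1.12 TPM (-2.34, adjusted p = 0.00415; sum -1.12, adjusted p = 0.577). Without glabrous 3, the vascular median was 0.00 (adjusted p = 0.427) and the stomatal one -0.28 (adjusted p = 0.0597).

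Glucosinolate genes had 6 higher and 5 lower copies of 71, and 8 and 5 adjusted over the list alone (median -0.36, mean -0.22, camera adjusted p = 0.826). The list's direction depended on 1 glabrous leaf. Without glabrous 1 its median was -1.64 (adjusted p = 7.06e-09), with 2 higher and 31 lower copies (5 and 46 adjusted over the list alone). Without glabrous 3 it was 0.98 (adjusted p = 1.35e-05), with 13 higher and 1 lower (25 and 3). Without hairy 1 there were 0 higher and 1 lower in limma (5 each way at an unadjusted p under 0.05), and without hairy 3 there were 2 and 1. With the 2-library filter the counts were 3 and 30 without glabrous 1, 21 and 0 without glabrous 3 (39 and 1 unadjusted), 2 and 4 without hairy 1 and 4 and 4 without hairy 3. In 97.2% of its copies glabrous 1 lay below glabrous 3, by a median of 2.21 on the log2 scale, while the hairy leaves differed by a median of 0.37. The C06 copy of SOT16 (BnaC06g063540.4DH), a sulfotransferase of glucosinolate synthesis, read 0.25 ± 0.19 TPM in the hairy and 29.1 ± 13.7 TPM in the glabrous line (-4.51, adjusted p = 1.42e-04). The A02 copy of the myrosinase TGG1 (BnaA02g053100.4DH) read 22.8 ± 4.30 against 1.88 ± 0.50 TPM (3.05, adjusted p = 9.66e-04). Neither gene's sum passed (0.47 and -0.86). The sum of MYB51, a regulator of indolic glucosinolates, did, at 18.0 ± 2.31 against 1.99 ± 1.89 TPM (2.83, adjusted p = 0.0148).

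Cell division genes went both ways, with 5 copies higher and 5 lower of 71, and 6 and 5 adjusted over the list alone (median -0.15, camera adjusted p = 0.684). The C08 copy of PCNA1 (BnaC08g078750.4DH), the replication clamp, read 168 ± 12.9 TPM in the hairy and 5.77 ± 2.42 TPM in the glabrous line (4.69, adjusted p = 1.86e-05). The C09 copy of MCM7 (BnaC09g001530.4DH), a replicative helicase subunit, read 0.23 ± 0.28 against 49.8 ± 14.3 TPM (-5.36, adjusted p = 3.19e-05). The log2 changes of their sums were -0.14 and -0.16, and neither passed. Of 29 endoreduplication copies, 2 were higher and 1 lower, also adjusted over the list alone (median -0.22). RBR1 (BnaA01g059920.4DH), the retinoblastoma homologue, read 10.7 ± 3.29 against 0.05 ± 0.07 TPM (3.45, adjusted p = 4.70e-04), and SMR1 (BnaC05g076150.4DH) 3.79 ± 0.21 TPM in the glabrous line, listed at 0 in both hairy leaves (adjusted p = 0.00291). The log2 changes of their sums were -0.23 and -0.63, and neither passed. Without hairy 1 the cell division list passed (median -0.51, adjusted p = 0.0462). It had 2 higher and 2 lower copies without hairy 1, without hairy 3 or without glabrous 1, and its median was 0.20 without hairy 3. With the 2-library filter there were 1 to 9 higher and 1 to 4 lower copies.

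Anthocyanin genes had 1 higher and 1 lower copy of 39, neither of which passed adjusted over the list alone (median 0.34). Both were TT19, a transferase that carries anthocyanin, at 13.2 ± 3.57 against 3.19 ± 2.06 TPM for the A10 copy (BnaA10g030010.4DH, 1.83, adjusted p = 0.0441) and 3.16 ± 1.33 against 15.9 ± 5.26 TPM for the C02 copy (BnaC02g006906.4DH, -2.02, adjusted p = 0.0193); the sum had 0.26 and did not pass. The call was lost in 12 of 17 alternative settings for the A10 copy and 7 of 17 for the C02 copy. Of 8 gibberellin copies 1 was higher, also adjusted over the list alone (median -0.26, mean 0.04): the receptor GID1A (BnaC05g081080.4DH), at 4.60 ± 2.42 against 0.24 ± 0.14 TPM (2.11, adjusted p = 0.0111). This copy lies in a dense run on C05, and the sum over GID1A copies had a log2 change of -0.68 and did not pass. Clock genes had 1 higher and 1 lower copy of 25, also adjusted over the list alone (median 0.10). PRR7 (BnaS00065g0200.4DH) read 23.6 ± 13.6 against 0.17 ± 0.19 TPM (4.29, adjusted p = 2.60e-04) and RVE8 (BnaC05g077210.4DH) 0.03 ± 0.04 against 5.85 ± 2.66 TPM (-2.68, adjusted p = 0.00216). Their sums had log2 changes of -0.27 and -0.24, and neither passed. No copy passed among 14 general epidermis copies (median 0.03, and -0.03 after quantile normalization) and 4 heat stress copies (median -0.22) in the limma fit, also adjusted over the list alone; at an unadjusted p under 0.05 there was 1 lower epidermis copy and no heat stress copy. None of the shoot meristem genes reached the filter. These lists did not pass the camera test.

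**Figure D2:**
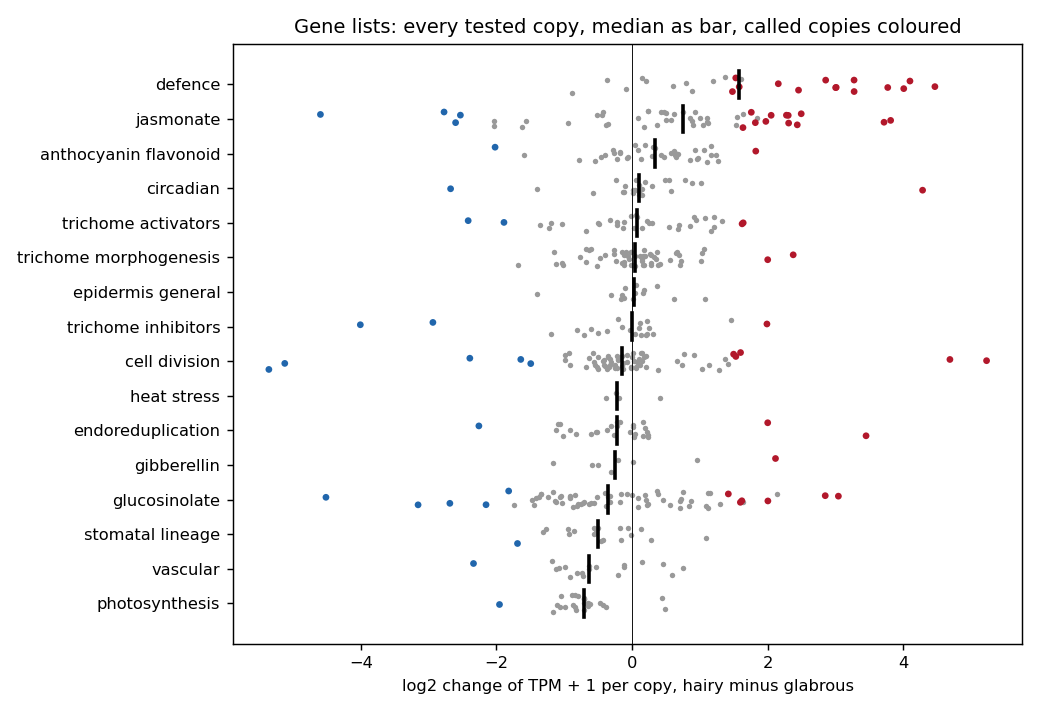
Log2 change of TPM + 1, hairy minus glabrous, for every tested copy of each gene list, with the median as a black bar and copies past the threshold in red (higher) or blue (lower). The defence list has the highest median, 1.58, and the photosynthesis list the lowest, -0.71.

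The largest differences were in single copies of very abundant genes. The 6 higher ones were the histone H3 copies BnaA02g055810.4DH (272 ± 79.7 against 0.38 ± 0.20 TPM, log2 change 7.60) and BnaC02g002280.4DH (456 ± 170 against 1.41 ± 0.29 TPM, 7.52), the histone H2B copy BnaC02g013400.4DH (422 ± 124 against 1.28 ± 0.42 TPM, 7.52), and the ribosomal protein copies BnaS00065g0260.4DH of S12/S23 (7.52), BnaC05g080660.4DH of L22e (7.49) and BnaA01g060490.4DH of S11 (7.43). The 6 lower ones were all ribosomal protein copies: BnaC06g058380.4DH of RPL10C (1.89 ± 0.61 against 504 ± 182 TPM, -7.41), BnaA10g035430.4DH of RPS6B (-7.29), BnaC03g058720.4DH of L27e (-7.14), BnaC01g029730.4DH of L15e (-7.10), BnaC05g077280.4DH of L29 (-7.10) and BnaS0015g00184.4DH of L13 (-7.04). Adjusted p-values ran from 1.77e-06 to 3.13e-06. Summed over all copies, the log2 changes of these genes were -0.18 to 0.32, and none of the sums passed in limma. On the log2(TPM + 1) scale, a copy near 0 TPM in one line can change only as far as its level in the other allows. Abundant copies therefore lead this ranking by construction. The copies on A01, A10, C01, C02, C05 and C06 lie in the dense runs described below. Those on A02 and C03 do not, and the others have no chromosome.

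The lines are near-isogenic, so the position of the calls along the chromosomes was compared with an even spread. Genes higher or lower in the hairy line lay in dense runs. On C06, 591 of 1666 tested genes were called (35.5%, Fisher's exact test, adjusted p = 1.75e-196), 563 of them lower. On A01, 349 of 2064 were called (16.9%, adjusted p = 1.45e-27), 308 of them higher. The lowest share was on C07, with 71 of 2398 (2.96%). Fisher's test counts genes as independent, which neighbouring genes need not be, and 556 of the genes called on C06 lie in 1 run. In the densest window of 50 genes, from BnaA01g059470.4DH to BnaA01g060720.4DH, all 50 were called, against at most 38% in any of 10000 shuffles (permutation p = 0.0001, the smallest they can give). Dense windows joined into 14 runs on 9 chromosomes with 2164 tested genes, of which 1580 were called (73.0%), or 36.7% of all calls. The longest, from BnaC06g045740.4DH to BnaC06g065980.4DH, held 635 tested genes, of which 554 were lower and 2 higher, and 490 of the lower ones had a hairy mean under 1 TPM. It holds the called copies of MYBL2, HDG11, JAZ2 and SOT16 on C06. Among the named list genes, other runs hold the called copies of RBR1 (A01), SMR1, RVE8 and GID1A (C05) and PCNA1 (C08). In leave-one-out fits that kept the filter at 2 libraries, A01 was not above the rest without hairy 1 (3.60%, adjusted p = 0.656) or without hairy 3 (3.26%, adjusted p = 0.555), nor C06 without glabrous 3 (10.7%, adjusted p = 0.351); this filter drops genes seen only in the line left with 1 leaf.

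**Figure D3:**
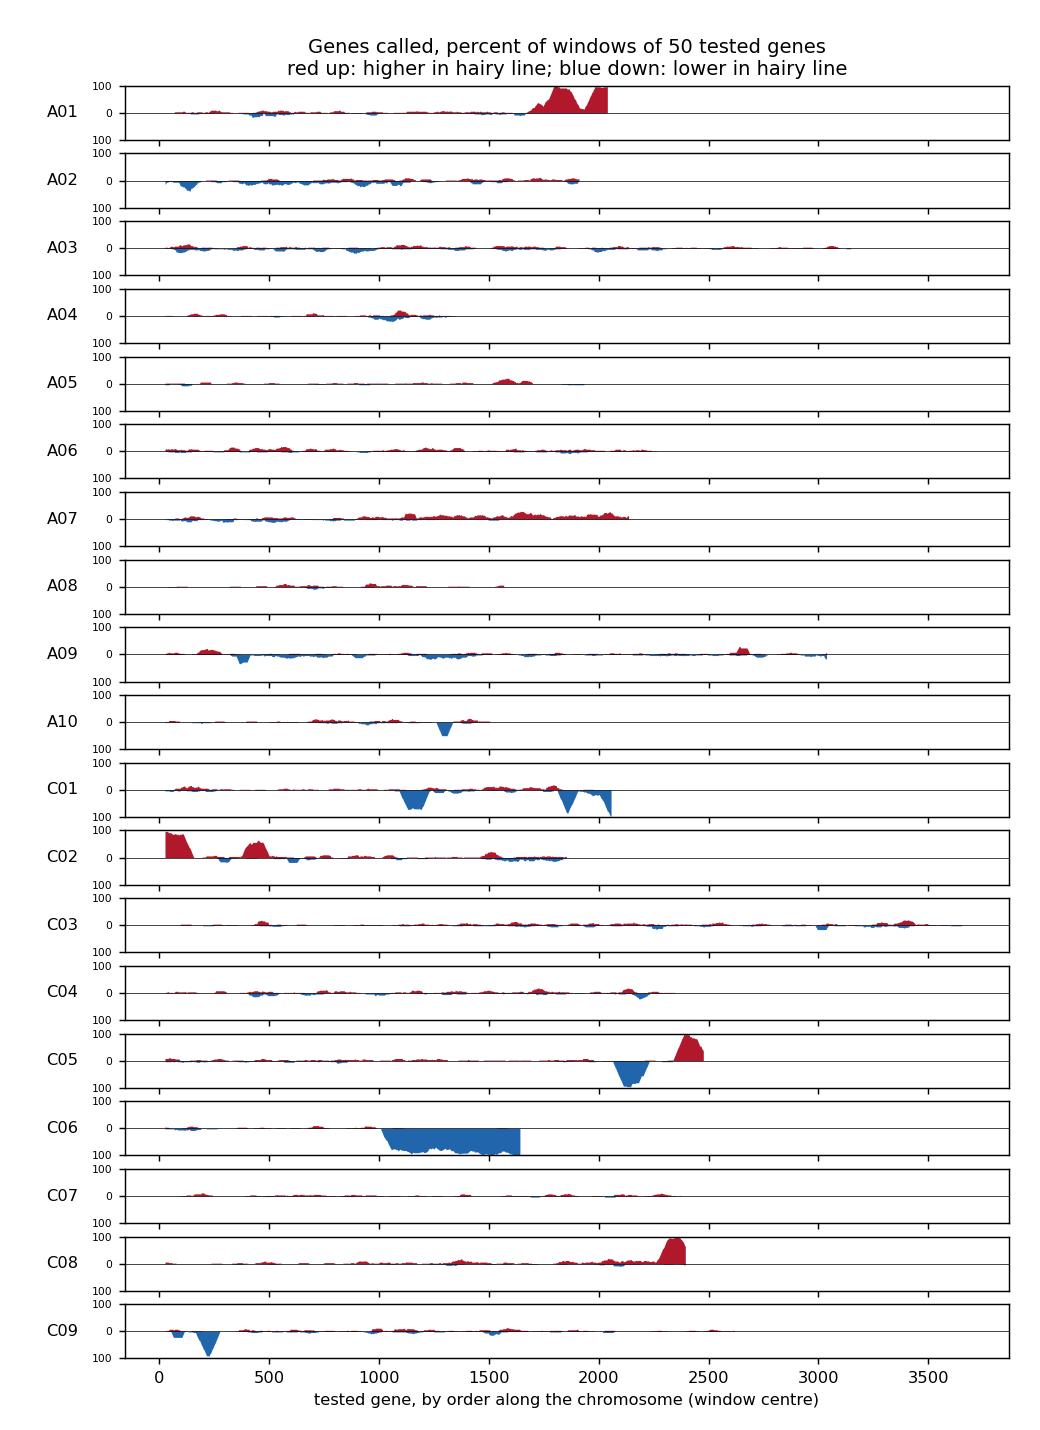
Share of genes called in sliding windows of 50 tested genes (percent, 0 to 100 each way) along the 19 chromosomes, by order of the gene identifiers; red upward for genes higher and blue downward for genes lower in the hairy line. Blocks of calls stand on 9 chromosomes, the longest on C06.

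Because near-identical copies can share reads, each gene was also compared with the other copies of the same Arabidopsis gene. Inside the runs, genes called lower had a median log2 change of -2.95, while their other copies had 0.56 and the sums -0.04. Genes called higher there had 2.85, their other copies -0.39 and the sums 0.11. Outside the runs, genes called higher had a median of 2.11, their sums 1.28, and 35.1% of those sums passed. The genes called lower there had -2.22 and their sums -0.35, of which 3.22% passed. Over all genes with several copies, 29.4% of the called ones had another copy called in the same direction (12.3% in shuffles). In the opposite direction it was 19.0% (12.2% in shuffles). The permutation p was 0.001 for each, the smallest that 1000 shuffles can give. For genes outside the runs the shares were 33.9% (8.34% in shuffles) and 10.7% (7.44% in shuffles). Shuffles moved calls gene by gene, so they ignore that calls cluster in runs. After summing copies, 295 of 15719 Arabidopsis genes were higher and 42 lower, and 3438 called copies belonged to a sum that was not called.

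**Figure D4:**
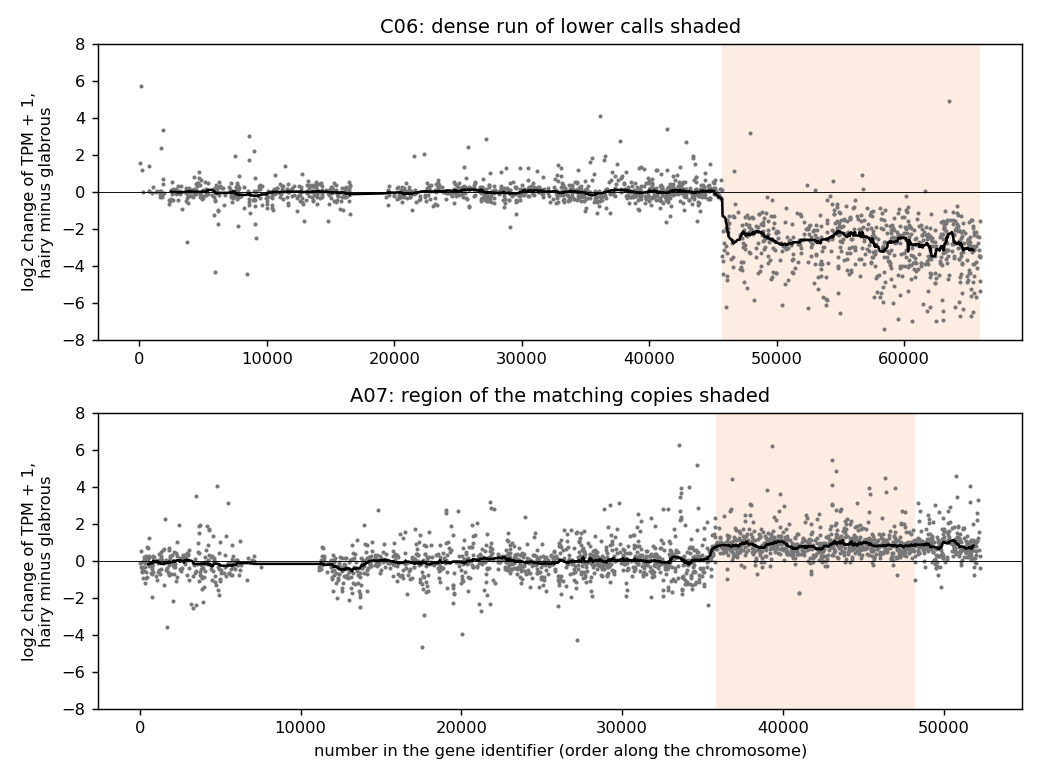
Log2 change of TPM + 1, hairy minus glabrous, of each tested gene on C06 (top) and A07 (bottom) against the number in its identifier, with a running median over 50 genes in black. The shaded part of C06 is the run of lower genes, and the shaded part of A07 spans the copies of the same Arabidopsis genes.

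Functional terms were tested to see which annotated families the calls fall in. WRKY transcription factors were higher, with 10 of 14 tested genes called (adjusted p = 2.43e-07), as were dehydrins, proteins of drought and cold responses, with 9 of 12 (adjusted p = 5.32e-07). WRKY18 (BnaC07g077590.4DH) read 114 ± 34.9 against 6.57 ± 0.21 TPM (3.89), and the WRKY53 copies on C07 (BnaC07g071370.4DH) and A03 (BnaA03g056320.4DH) changed by 3.40 and 3.22. The dehydrin ERD10 had copies on A06 (BnaA06g017770.4DH, 366 ± 234 against 33.6 ± 12.9 TPM, 3.30) and A07 (BnaA07g021760.4DH, 3.17), and ERD14 (BnaA07g048500.4DH) changed by 2.70. The lower terms with the smallest p were recognition of the 3'-splice site and rRNA processing, with 6 of 10 genes each (adjusted p = 3.74e-04). Outside the dense runs the first kept 6 of 10. The second has a member in the C06 run, so it had fewer than 10 genes there and could not be tested. In the first, BnaC03g092320.4DH read 0.05 ± 0.07 against 33.4 ± 6.82 TPM (-5.02), and BnaC03g091930.4DH and BnaC03g092110.4DH, at 30.0 ± 2.80 and 27.1 ± 7.29 TPM in the glabrous line, are listed at 0 in both hairy leaves. In the second, the RNA-binding copies BnaC04g078122.4DH and BnaC06g065680.4DH changed by -6.62 and -4.12, and the histone deacetylase HD2A (BnaA02g010330.4DH), at 12.2 ± 0.26 TPM in the glabrous line, is listed at 0 in both hairy leaves. In total 25 terms were higher and 4 lower of 861 tested. Each gene was given 1 free-text description, so terms share no genes, but a family can be split over several terms. Members of a term can be copies of 1 gene, as for WRKY53 and ERD10, and are not independent. Leaving out hairy 1, hairy 3 or glabrous 1 left fewer higher terms. After summing copies none of 185 terms passed. Copies of 1 gene count once there, so fewer terms reach 10 genes and small ones could not be tested. Among the members named here, the sums of WRKY18 (3.52), WRKY53 (3.46), ERD10 (2.75), ERD14 (1.85) and HD2A (-2.86) passed in limma. That of the RNA-binding copies (-1.23) did not, and the splice-site genes named have no Arabidopsis match.

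Among the other named genes that passed, the call was lost in 5 of 17 alternative settings for PSBO1, 4 of 17 for PIR, 4 of 14 for SMR1, 3 of 14 for ETC3, SIM, XCP2 and GID1A, and 3 of 17 for ERD14. It was lost in 2 of 17 for both ERD10 copies, 2 of 14 for RVE8 and 1 of 17 for TGG1. For 31 of the 51 named genes that passed it was lost in none of the settings in which they were tested.

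The deposited table carries its own test per transcript. Of 79668 transcripts with a p-value, 1596 were higher and 1627 lower in the hairy line at an adjusted p under 0.05. They belong to 3035 genes, of which 3000 were tested in the limma fit and 2657 called. A further 1644 genes were called by limma without such a transcript. The sign was the same for 3108 of 3188 transcripts that could be compared.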

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

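The crossed pairing, the transcripts and the summed copies for gene counts, all settings for chromosomes, terms and copies, and the leave-one-out fits with a 2-library filter were chosen after seeing the data. The plan words the filter as the size of the smaller group, 1 leaf in these fits. The first version required 2 libraries, which drops genes seen only in the line with 1 leaf, and it was changed after its results had been seen. A lone leaf is assumed to vary like the leaves of the other line. Over both versions, higher genes (2319 with all leaves) ran from 508 to 3423 and lower genes (1982) from 641 to 1539; with the planned filter higher genes ran from 723 to 2314. Counts over 2-fold had the same ranges. C06 held 10.7% to 28.0% called genes and A01 3.26% to 20.3%. C06 lost its call without glabrous 3 (10.7%), and A01 lay below the other chromosomes, not past the threshold, without hairy 1 (3.60%) and without hairy 3 (3.26%), each with the 2-library filter. List medians ran from -0.54 to 0.20 for cell division, -1.64 to 1.07 for glucosinolate (0.98 and 1.07 without glabrous 3), 0.22 to 1.33 for jasmonate, -1.07 to -0.61 for photosynthesis (call lost at -0.68 without hairy 1 with the 2-library filter), -0.73 to -0.24 for stomatal lineage, -1.25 to 0.00 (0.00344) for vascular and 1.13 to 2.03 for defence genes. With the 2-library filter the stomatal call was lost without hairy 1 (adjusted p = 0.241) and hairy 3 (0.209), and the vascular call without hairy 1 (0.113), hairy 3 (0.209) and glabrous 3 (0.733). With the planned filter both were lost without glabrous 3. Lists that did not pass in these fits ran from -0.12 to 0.44 (trichome activators), -0.21 to -0.03 (inhibitors), -0.19 to 0.35 (morphogenesis), 0.07 to 0.45 (anthocyanin), -0.36 to 0.09 (endoreduplication), -0.80 to 0.21 (gibberellin), -0.27 to 0.57 (circadian), -0.51 to 0.45 (epidermis) and -0.67 to 0.51 (heat stress). Terms ran from 3 to 32 higher and 2 to 10 lower. At 5 TPM or more, 1251 genes were lower, 13 terms higher and 0 lower. Transcripts gave 1195 higher and 1138 lower, and summed copies 295 and 42, with 0 terms each way. With no filter 6 terms were higher, and 16 without a variance trend. With no filter the jasmonate median was 0.40, its call lost, and the defence median 0.65, its call kept. The stomatal median was -0.48 at 5 TPM and -0.56 at a pseudocount of 0.1, and the vascular one -0.92 at 5 TPM and -0.38 for summed copies, none past the threshold. With an estimated correlation no list passed, at unchanged medians of 1.58 (defence), 0.76 (jasmonate), -0.71 (photosynthesis), -0.51 (stomatal) and -0.64 (vascular). Except for the filters, the cause was not tested. Depth is unknown, so its limit cannot be given.

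With the replicate number as a block, the stomatal (-0.51) and vascular (-0.64) lists lost their calls and 16 terms were higher. Pairing hairy 1 with glabrous 3 instead gave 3921 higher (3785 over 2-fold) and 3039 lower genes.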

Other observations

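Among the 295 Arabidopsis genes whose sum over copies was higher in the hairy line and the 42 whose sum was lower, those named here were chosen after their values were seen, and no test of a group was made on them. Their limma adjusted p-values ran from 1.98e-04 to 0.00604. Of the 6 sums of the defence list, 3 were not called. WRKY62 read 22.6 ± 2.93 TPM in the hairy and 0.08 ± 0.02 TPM in the glabrous line (SD, n = 2 leaves each; log2 change 4.44). NIMIN1, which binds the salicylate regulator NPR1, read 39.0 ± 5.92 against 0.89 ± 0.93 TPM (4.49), and CBP60G, a regulator of salicylate synthesis, 45.0 ± 16.3 against 1.72 ± 0.13 TPM (4.03). WRKY38, WRKY41, WRKY54 and WRKY40 had log2 changes of 4.08, 4.03, 3.70 and 3.00. PEN1, PEN2 and PEN3, which act in resistance to fungal entry, had 2.65, 2.59 and 3.15. The desiccation gene RD29B read 584 ± 84.8 against 91.8 ± 5.24 TPM (2.65). Lower in the hairy line were the flowering repressor FLM, at 0.23 ± 0.02 against 33.7 ± 0.85 TPM (-4.82), and the linker histone HIS1-3, at 3.27 ± 0.85 against 47.0 ± 9.82 TPM (-3.49).

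The tests of explanations in the paragraphs that follow were chosen after the results were seen; the counts, sums and list tests of defence genes were planned. The run of lower genes on C06 was noticed in the data, and the tests of it were revised after results were seen. Copies of its genes in a region of A07 had a median log2 change of 0.85 (bootstrap 95% interval 0.815 to 0.881; 94.9% higher), which argues against a loss of C06 copies with no gain elsewhere. If reads of altered C06 copies went to A07, the C06 to A07 ratio in the glabrous line would predict each A07 gain. The observed gain would then rise with the predicted gain at a slope of 1. Divided by the correlation of the predicted gain between the glabrous leaves (0.846), the slope was 0.305 (0.0799 to 0.556). This argues against such reads as the whole cause and leaves a part open. A hypothesis is that the C06 segment may be replaced by a further copy of the A07 segment. In that region, 14 A07 genes with no match in the C06 run had a median of 0.76 (0.488 to 0.918), 14 of 14 higher. Copies elsewhere on C06 or on unplaced scaffolds were not excluded. The lines' design does not test this hypothesis. The bootstrap intervals resample genes or pairs of copies, not leaves.

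Other forms of these tests were run. A looser match gave 99 A07 genes with a median of 0.83 (0.67 to 1.04; 93.9% higher). The slope was 0.267 with the same libraries on both axes, 0.135 and 0.382 with either split, and 0.258 (0.0641 to 0.469) averaged, over 300 pairs. In sets of 75 pairs, from the lowest to the highest C06 share, the observed A07 gains were 0.65, 0.74, 0.74 and 0.59, against 0.65, 0.86, 1.00 and 1.35 if reads moved. For 13 of 14 runs the partner copies had a median opposite to the run. These runs are not independent, because partner copies of some lie inside other runs, 41 of 42 for the A02 run and 8 of 8 for the A10 run. For the C01 runs from BnaC01g067640.4DH and BnaC01g074120.4DH it was 72 of 79 and 69 of 74. It was 125 of 198 for the A01 run from BnaA01g057980.4DH and 40 of 123 for the C02 run from BnaC02g000030.4DH. The direction of partner copies inside runs follows from how the runs were chosen. Pooled over the other runs, 904 partner copies outside runs moved opposite by 0.76. The 1337 genes with no match in the run moved opposite by -0.06 (-0.0911 to -0.0423), which taken alone goes against the pattern. Of these, 1317 lie in the widest region (-0.07), and the other 20 had 1.04 (0.521 to 1.21). This split was made after seeing the pooled value. The widest region, on C03, was set by 54 copies of genes of the A01 run from BnaA01g063120.4DH. Those copies had a median log2 change of 0.09 (-0.018 to 0.216), in the run that did not follow the pattern. Genes of that region thus cannot show whether unmatched genes move where partner copies do.

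Of 25 copies of defence genes 14 were higher in the hairy line, and of their 6 sums 3 were. With an estimated correlation the list's camera p was 0.0833, and 0.984 after adjustment, the value of every tested list. Reads moved between copies of a gene would leave the sums unchanged, and the median log2 change of the 6 sums was 1.85 (from -0.94 for PR1 to 3.13 for PR2), which argues against it. A difference in leaf stage could contribute: sums of photosynthesis genes had a median of -0.84 and those of cell division genes -0.09, and stage cannot be told apart from line, since the labels give no finer stage per leaf. A difference in harvest time could not be excluded either: the clock sum with the largest change was LHY, at 0.83 (SE 0.526). A difference between the lines stays open, untested.

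Hairy 1 deviated from its line as glabrous 3 did, and the deviations of leaves with the same number correlated at -0.407 across genes, which are not independent. A check of gene length is void, because only 64.5% of tested genes matched a gene with a length, so a length bias stays open. A different share of dividing cells would move replication genes and histones together, but in the contrast of hairy 1 and glabrous 3 against the others MCM genes had a median of 0.73 and histones of -0.73, a difference of 1.46, which argues against it as the whole cause. In that contrast the median of all genes was 0.34 (SD 0.544), that of kinesins 0.82, of myosins 0.78 and of ribosomal proteins -0.51.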
